A study of Mus musculus with 15 samples.

How the data were processed

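Total RNA from whole blood of 15 mice was analysed, 5 given vehicle, 5 given ABBV-075 at 1 mg/kg and 5 given it at 5 mg/kg, each sampled after 6 h. Per the labels' protocols, RNA was extracted with Qiazol and RNeasy and biotin-labelled cRNA was made from 200 ng with an Affymetrix 3' IVT kit. The deposited values are intensities per probe set on a linear scale, with negative values, as read from the values themselves, since the software, the summarisation method and any normalisation were not given in the sources used here. The table holds 45101 probe sets and 1 column per array. The intensity values deposited by the authors were not scaled to a common level between arrays: the array medians ran from 3.61 to 25.4 while the Cre spike-in ran from 11780 to 17150.

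The design was fixed before the data were examined and had taken the deposited values to be normalised between arrays. As they were not, quantile normalisation, written beforehand as an alternative, became the standard setting, and the values without scaling became an alternative. The 64 control probe sets were left out before quantile normalisation, values under a floor of 16 were set to 16, and log2 was taken. The floor and the rule that a gene lie above it on at least 5 arrays were chosen after the value distribution was seen and before any test. Of the probe sets, 34945 were annotated with 1 gene, 932 with several and 9160 with none listed, and only the first kind was named. They covered 18194 genes, of which 12499 were tested and 5695 were too dim. The annotation table can be old, and 0 symbols changed on matching through Entrez identifiers. Each gene was represented by its probe set of highest mean. Probe sets can match related transcripts, those ending in _x_at or _s_at above all, and read mainly the 3' end. Probe set identifiers are kept in the tables, and genomic positions were not used here.

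Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, without trend or robust options) on all 15 arrays with group means as the terms, 12 residual and 3.904 prior degrees of freedom, and Benjamini-Hochberg adjustment over the tested genes. The threshold was an adjusted p of 0.05. The median standard error of a log2 fold change was 0.289. The contrasts were each dose against vehicle and 5 mg/kg against 1 mg/kg.

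The named-gene rule, fixed beforehand, took for each dose the 10 genes that rose and the 10 that fell by the largest log2 fold change among those past the threshold, with all 5 treated arrays on one side of the vehicle arrays, a mean in the higher group at or above the median of all genes and a symbol that is not a clone or predicted name. For the dose difference it took 5 in each direction. It added Hexim1, Serpini1, Zcchc24, Zmynd8, Brd2, Brd3, Myc, Ccr2, Cd180 and Il7r, and up to 4 members per list with the smallest p at 5 mg/kg. All 11 genes past the threshold met the rule. Genes named beyond it are said to be so where they appear, and the members quoted per list were picked from those the rule allows with their values in view. Part of what the rule covers is not reported here.

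The 27 lists, fixed beforehand, held 540 genes, of which 471 matched a probe set and 405 were tested. They were BET inhibitor markers of this study, BET inhibitor response in other studies, BET proteins and P-TEFb, histones, MYC and ribosome biogenesis, inflammatory cytokines and NF-kB, interferon-stimulated genes, glucocorticoid-induced genes, immediate-early genes, circadian clock, cell cycle, p53 targets, BCL2 family and survival, autophagy and lysosome, heat shock, ribosomal proteins, housekeeping genes, and markers of B cells, T cells, NK cells, mature neutrophils, immature neutrophil granules, monocytes, dendritic cells, eosinophils and basophils, platelets and erythroid cells. BET inhibitor response in other studies shared 7 members with other lists, histones 4 and the monocyte markers 0. Whole blood can hold all of these cell types, and a marker of a given type can also be expressed by others. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the 27 lists in each comparison. Camera compares a list with all other genes. Fry's directional p asks whether members move on balance one way and its mixed p whether they change in either direction, and neither compares a list with other genes.

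Array measures were compared by exact two-sided permutation tests over all 126 splits of 5 against 5, with adjustment over 66 tests. The share of values at the floor, also computed at an earlier stage, was dropped from that family after its tests were seen because quantile normalisation makes it nearly constant. The overlap of the doses was set against 100 simulations of unchanged groups sharing the vehicle arrays, with genes drawn independently. It was also set against 20 splits of the vehicle arrays. For other splits of the arrays, 100 of the 126 were drawn with a fixed seed.

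Alternatives fixed beforehand were median and 75th percentile scaling, the brighter 50% of genes, the mean of a gene's probe sets, avoidance of _x_at and _s_at sets, each probe set counted on its own, trended and robust variance, array weights, only the groups compared, the replicate number as a block, marker means of erythroid cells, mature neutrophils or B cells as covariates, an absolute log2 fold change of 1, an adjusted p under 0.01, and leaving out each array. Alternatives chosen after the data were seen were no scaling, floors of 8 and 32, genes above the floor on at least 1 array, omission of the dimmest and the brightest array, omission of the 2 vehicle arrays of highest 18S signal, and log2 18S as a covariate. To test scaling as the source of the monocyte marker shift, each marker's log2 value on the unscaled arrays was taken less the mean of the 50 tested genes nearest to it in mean brightness on the same array, and the mean over markers was compared between 5 mg/kg and vehicle by exact permutation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

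The gene test was tested on simulated data for 5 mg/kg against vehicle, with 12499 genes, 20 runs and 200 changed genes per run. It found 26% of the genes changed by 1 on the log2 scale and 72.8% of those changed by 2, 5.23% of calls were false, and the unchanged 1 mg/kg group gave 0.05 calls on average. The adjusted threshold is easier to reach with 200 changed genes than where fewer change. The shares found can therefore be too high for the real arrays. A list shifted by 0.5 was found in 100% of runs, with 0.1 unshifted lists called on average. The simulated genes varied independently, unlike members of the real lists. The list figures therefore do not carry over to the real arrays, where other splits at 5 mg/kg gave a median of 3 lists.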

Results

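RNA from mouse whole blood was profiled 6 h after dosing with vehicle or ABBV-075 (mivebresib), an inhibitor of the BET bromodomain proteins, which bind acetylated histones and include Brd2 and Brd3. The 15 mice formed 3 groups of 5, given vehicle, a dose of 1 mg/kg and a dose of 5 mg/kg, with 1 Affymetrix mouse expression array per mouse. The stated purpose of the series was to look for blood markers that respond to the compound. Array intensities were not on a common scale: the median probe set intensity ran from 3.61 (1 mg/kg replicate 1) to 25.4 (1 mg/kg replicate 4), while the Cre hybridisation spike-in ran from 11780 to 17150. After quantile normalisation 52.7% of probe set values lay at the floor of 16, and 12499 of 18194 genes were above it on at least 5 arrays and were tested. The number of arrays, 5 per group, limits the precision of every comparison. Across the tested genes, the log2 values of pairs of arrays correlated at 0.675 to 0.921, over genes that are not independent replicates. The median SD within a group was 0.39 on the log2 scale for vehicle, 0.50 at 1 mg/kg and 0.40 at 5 mg/kg. Xist was high and the Y-linked genes were at or near the floor on all 15 arrays.

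Several blood cell markers and the ribosomal RNA signal were lower on average on the treated arrays. The mean log2 value of the monocyte markers was 7.82 ± 0.16 (SD, n = 5) with vehicle, 7.16 ± 0.26 at 1 mg/kg and 7.05 ± 0.19 at 5 mg/kg. All 5 arrays of each dose lay below all 5 vehicle arrays (exact two-sided permutation p = 0.00794 at each dose, the smallest that splits of 5 against 5 allow; adjusted p = 0.131 over 66 tests). The mature neutrophil marker mean was 7.14 ± 0.27 with vehicle, 6.65 ± 0.31 at 1 mg/kg and 6.71 ± 0.32 at 5 mg/kg (exact permutation p = 0.0397 at each dose; adjusted p = 0.262). Dendritic cell markers averaged 7.11 ± 0.19 with vehicle, 6.52 ± 0.43 at 1 mg/kg and 6.79 ± 0.26 at 5 mg/kg (exact permutation p = 0.0238 and 0.0556, adjusted p = 0.262 and 0.276). Eosinophil and basophil markers averaged 6.63 ± 0.29 with vehicle, 6.40 ± 0.21 at 1 mg/kg and 5.95 ± 0.39 at 5 mg/kg (exact permutation p = 0.206 and 0.0238, adjusted p = 0.524 and 0.262). The log2 signal of the 18S ribosomal RNA control probe sets was 11.19 ± 0.94 with vehicle, 9.97 ± 0.43 at 1 mg/kg and 9.42 ± 0.42 at 5 mg/kg (exact permutation p = 0.0397 and 0.00794; adjusted p = 0.262 and 0.131). The log2 difference between the 3' and 5' control probe sets of Actb, a sign of RNA integrity, was 0.71 ± 0.18 with vehicle and 0.61 ± 0.16 at 5 mg/kg (exact permutation p = 0.365). None of the 66 array-quality tests passed an adjusted p of 0.05. That is not evidence that the arrays were alike, since even the smallest exact permutation p possible, 0.00794, became 0.131 on adjustment.

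**Figure D1:**
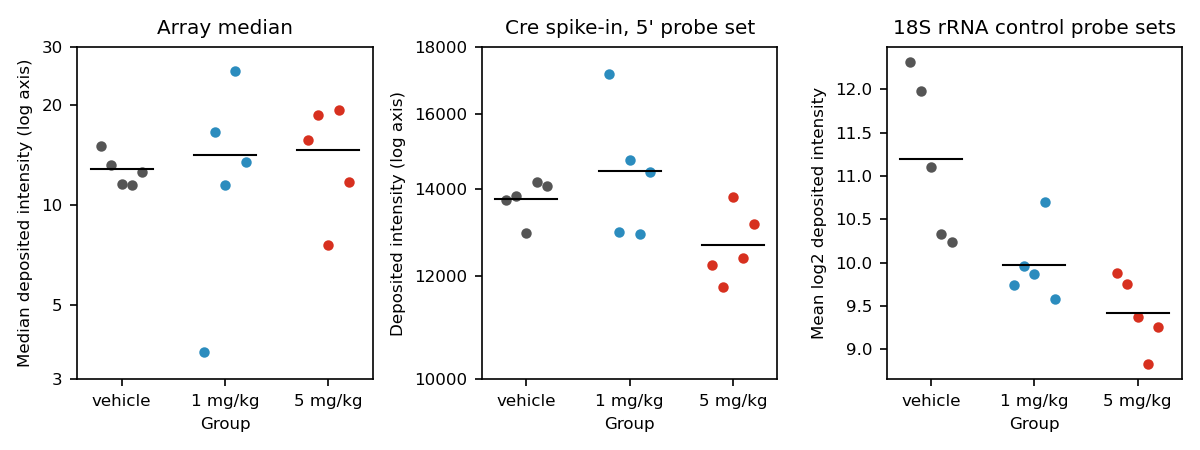
Median probe set intensity, Cre spike-in intensity and log2 18S signal of each of the 15 arrays by group (points, 1 per mouse; bars, group means). The median ran from 3.61 to 25.4 and the spike-in from 11780 to 17150, and the mean log2 18S signal was 11.19 with vehicle, 9.97 at 1 mg/kg and 9.42 at 5 mg/kg.

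At 5 mg/kg against vehicle, which asks what the higher dose does to blood transcripts, 3 genes rose and 8 fell. Sertad1, a transcriptional regulator that binds the cyclin-dependent kinase CDK4, rose 6.31-fold (log2 2.66 ± 0.31, SE, n = 5 per group; limma adjusted p = 0.00138), and the histone genes H2ax and H2aw rose 2.76-fold (1.46 ± 0.22; adjusted p = 0.00998) and 2.39-fold (1.26 ± 0.23; adjusted p = 0.0485). Among those that fell were Pla2g7, the secreted hydrolase of platelet-activating factor, 5.85-fold (-2.55 ± 0.39; adjusted p = 0.00998), Clec4a3, a C-type lectin receptor, 4.75-fold (-2.25 ± 0.30; adjusted p = 0.0043), Mpeg1, the pore-forming perforin-2 of macrophages, 4.65-fold (-2.22 ± 0.31; adjusted p = 0.0043), and the chemokine receptor Ccr1 4.28-fold (-2.10 ± 0.35; adjusted p = 0.0236). Dpagt1, the enzyme that starts assembly of N-linked glycans, fell 3.15-fold, the receptor phosphatase Ptpro 3.14-fold (adjusted p = 0.0043 for each) and the mitochondrial ATP carrier Slc25a24 2.24-fold (adjusted p = 0.0485). At 5 mg/kg Ptpro was above the floor on 2 of 5 arrays, Dpagt1 on 3, and Clec4a3 and Pla2g7 on 4, and with vehicle Sertad1 was on 4 of 5, so these folds depend on where the floor was set. The calls of H2aw, Slc25a24 and Ccr1 were the least stable. Leaving out each of the 15 arrays in turn lost them in 11, 11 and 8 runs. Over all alternatives they were lost in 22 of 34, 21 of 33 and 14 of 34, with log2 values of 0.41 to 1.47, -1.24 to -0.58 and -2.30 to -1.15. Ear3, a ribonuclease of the eosinophil-associated family, was at the floor on all 5 arrays at 5 mg/kg and so at least 9.97-fold lower than with vehicle (log2 mean 7.32 ± 0.38 with vehicle, SD, n = 5; adjusted p = 5.8e-04). Its probe set carries the suffix of sets that match related transcripts, so other members of that near-identical family can contribute to the signal.

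Their Entrez Gene identifiers were 55942 (Sertad1), 15270 (H2ax), 319162 (H2aw), 27226 (Pla2g7), 73149 (Clec4a3), 17476 (Mpeg1), 12768 (Ccr1), 13478 (Dpagt1), 19277 (Ptpro), 229731 (Slc25a24) and 53876 (Ear3). For each of the 11 genes all 5 arrays at 5 mg/kg lay on one side of all 5 vehicle arrays. At an adjusted p under 0.1 there were 36 genes, 12 higher and 24 lower, and at an unadjusted p under 0.05 there were 972, 439 higher and 533 lower, against 625 from chance alone. The count and its balance depended on the processing. They were 27 higher and 38 lower with array weights, 21 and 24 with a floor of 32, 11 and 22 with the mean of a gene's probe sets and 11 and 11 with genes above the floor on at least 1 array. Groups without overlap were seen for 2.57% of genes, where chance gives 0.794%. The other probe set of Ccr1, near the floor, gave -0.19 and that of H2aw 0.41. Log2 18S signal was lower at 5 mg/kg by the values above, and 0 genes passed with it as a covariate (limma; 1077 at an unadjusted p under 0.05). The 11 genes kept their signs there, with a median absolute log2 fold change of 1.99 against 2.10. Their median SE was 0.468 against 0.304. Sertad1, Ear3 and Akirin1, the last named after its value was seen (2.56 with all arrays, 0.22 in its other probe set), passed without the 2 vehicle arrays of highest 18S signal, Sertad1, Ear3 and H2ax with the mature neutrophil marker mean as a covariate, and Ear3 alone without scaling between arrays (0 higher, 1 lower), where the median of all genes was 0.102. The count rose to 19 without 1 mg/kg replicate 1 and 22 without 1 mg/kg replicate 5, arrays outside this comparison that share its normalisation, gene filter and estimate of spread. Which of these mattered was not tested.

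**Figure D2:**
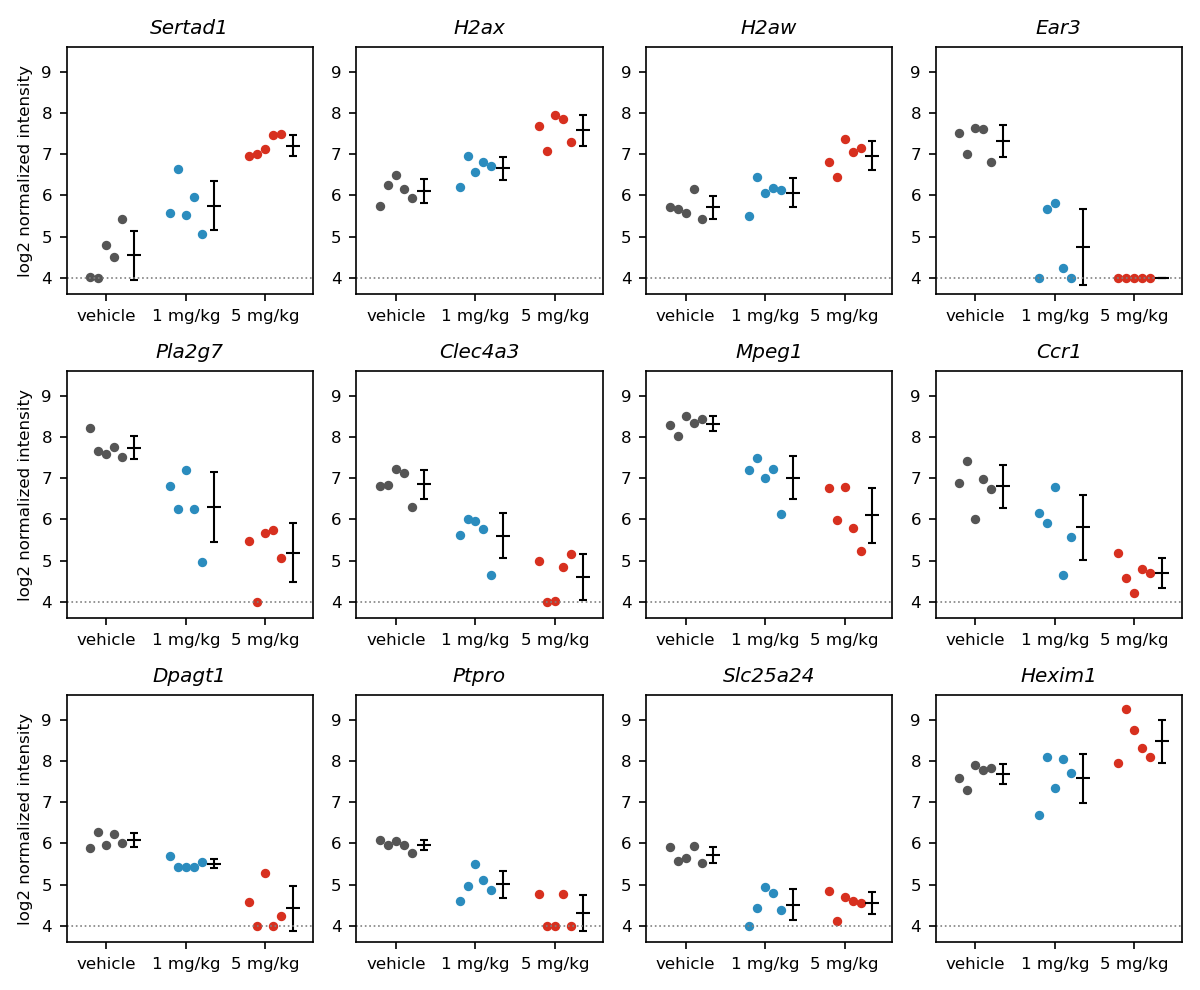
Normalised log2 values of the 11 genes past the threshold at 5 mg/kg and of Hexim1 on each array (points), with group mean and SD (n = 5) and the floor at 4 as a dotted line. Ear3 averaged 7.32 with vehicle and lay at the floor at 5 mg/kg, and Sertad1 averaged 4.55 with vehicle, 5.75 at 1 mg/kg and 7.21 at 5 mg/kg.

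Monocyte markers as a group fell at 5 mg/kg. Of 16 measured members 15 were lower than with vehicle, the median log2 difference was -0.82, 10 passed when adjusted over the list alone and 0 over all genes. Cd68, a lysosomal glycoprotein of macrophages, gave -1.34 ± 0.33 (SE, n = 5 per group), Fcgr4, an IgG receptor, -1.22 ± 0.33, Ms4a6c -0.91 ± 0.25 and Cybb, the catalytic subunit of the phagocyte oxidase, -0.88 ± 0.23, none past the threshold over all genes. Camera's adjusted p was 5.0e-11 with the preset correlation, and adjusted p = 0.0152 with an estimated correlation. Fry, which does not compare a list with other genes, gave an adjusted p of 0.00133 for one direction and 1.7e-05 for either direction. Ccr2, the chemokine receptor that draws monocytes out of the marrow, is outside that list and gave -1.77 ± 0.37 (adjusted p = 0.0905), with -2.62 and 0.18 in 2 other probe sets. The log2 18S signal was lower on the same arrays, and the estimated-correlation call was lost with it as a covariate (median -0.67; adjusted p = 0.175 with an estimated correlation), without the 2 vehicle arrays of highest 18S signal (median -0.80; adjusted p = 0.11) and without scaling between arrays (median -0.73; adjusted p = 0.817). Under those settings the preset camera gave an adjusted p of 2.7e-04, 6.0e-08 and 7.1e-11 and fry 0.0463, 0.00824 and 0.953.

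The other myeloid and granulocyte lists did not hold with an estimated correlation. Mature neutrophil markers had a median of -0.35, with 3 of 13 members lower when adjusted over the list alone, among them the formyl peptide receptor Fpr2 (-1.34 ± 0.27, SE) and the lectin receptor Clec4e (-1.06 ± 0.23) (camera adjusted p = 0.00734, adjusted p = 0.322 with an estimated correlation). Immature neutrophil granule markers had a median of -0.15, 1 member higher and 1 lower when adjusted over the list alone (Chil3, a chitinase-like protein, -1.50 ± 0.45), and a camera adjusted p of 0.703. Dendritic cell markers had a median of -0.21 (camera adjusted p = 0.0794), with Ccr9, a homing receptor, at -1.36 ± 0.32 and Tcf4, the transcription factor of plasmacytoid dendritic cells, at -0.80 ± 0.25. Eosinophil and basophil markers, 5 of them measured, had a median of -0.68 (camera adjusted p = 0.0794), with the lipoxygenase Alox15 at -2.14 ± 0.72 and Gata1 at -0.68 ± 0.23. None of these members passed over all genes.

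Histone genes as a group rose at 5 mg/kg. Of 11 measured members 10 were higher, with a median of 0.48, and 2 passed over all genes (H2ax and H2aw) and 3 when adjusted over the list alone, the other being H3f3a, a replication-independent H3 gene (1.03 ± 0.35, SE). Camera's adjusted p was 2.9e-06, and adjusted p = 0.0391 with an estimated correlation. Fry's adjusted p was 0.00506 for one direction. The estimated-correlation call was lost, at adjusted p = 0.0551 to 0.108, without vehicle replicate 1, 2, 3 or 5, without 1 mg/kg replicate 1, 3 or 4, and without 5 mg/kg replicate 1, 3 or 5, while the median was 0.417 to 0.545 and fry's adjusted p 0.00661 to 0.0198. It was also lost with the 18S signal as a covariate (median 0.45; adjusted p = 0.188; fry 0.0831), without scaling between arrays (median 0.59; adjusted p = 0.832; fry 0.953) and in all under 9 of 18 settings other than leaving out arrays in turn.

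Among genes of the compound's target pathway, Brd2, a BET protein, was at 1.26 ± 0.23 (SE, n = 5 per group; 2.39-fold; adjusted p = 0.058, or 0.0446 when each probe set was counted on its own) and at 1.31 in its other probe set, and Brd3 at -0.20 ± 0.36. The list of BET proteins and of P-TEFb, the kinase that releases paused RNA polymerase, had a median of 0.23 over 20 members, with 0 past the threshold over all genes and 1, Brd2, when adjusted over the list alone (camera adjusted p = 0.00734, adjusted p = 0.1 with an estimated correlation; fry adjusted p = 0.0682). Hexim1, which holds P-TEFb inactive, was at 0.79 ± 0.29 (adjusted p = 0.466) in its brighter probe set and at 1.86 ± 0.29 in a dimmer one, which passed when each probe set was counted on its own (adjusted p = 0.0128). Serpini1, a serine protease inhibitor, was at 0.75 ± 0.28 (adjusted p = 0.484) but above the floor on 1 of 5 arrays with vehicle and 4 of 5 at 5 mg/kg, so that its value depends on the floor. Its other tested probe set gave 0.30 ± 0.23. Zcchc24, a zinc finger gene, was at -0.49 ± 0.28 (adjusted p = 0.743) and Zmynd8, a reader of histone marks, at -0.12 ± 0.21 (adjusted p = 0.947), turning to 0.0056 without scaling between arrays and reaching -1.09 in another probe set. These 4 markers were chosen by the study in part on these samples, so the 2 of them past the threshold when adjusted over the list alone (Hexim1 and Serpini1; 0 over all genes) are not independent evidence, and their list had a median of 0.31 and a camera adjusted p of 0.263.

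Genes known from other studies to respond to BET inhibitors moved in opposite directions. Of 13 measured members 1 rose (Sertad1) and 1 fell (Ccr1) over all genes, and 2 were higher and 4 lower when adjusted over the list alone. Those 6 included Txnip, the thioredoxin-interacting protein (0.80 ± 0.25, SE), Il7r, the interleukin-7 receptor (-0.64 ± 0.20), Myc (-0.94 ± 0.36) and Ccr2. The median was -0.49 (camera adjusted p = 0.183), and fry's adjusted p was 0.286 for one direction and 2.7e-09 for either direction. The tests did not use the direction in which other studies saw each member move. The median and the one-direction tests therefore cannot decide whether the members moved as known. Cd180, a receptor of B cells, was at -0.33 ± 0.23 (adjusted p = 0.817).

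Of the remaining lists at 5 mg/kg, none held with an estimated correlation, and 0 of their members passed over all genes. Interferon-stimulated genes had a median of -0.30, with Rtp4 at -1.12 ± 0.28 (SE) and Gbp3 at -0.85 ± 0.21, the 2 lower members when adjusted over the list alone (camera adjusted p = 0.0215, adjusted p = 0.322 with an estimated correlation). Heat shock genes had a median of 0.12, with the chaperone Hsp90aa1 at 0.85 ± 0.21 (camera adjusted p = 0.0248, adjusted p = 0.383 with an estimated correlation). Ribosomal protein genes had a median of 0.19 over 25 members, Rps6 being at 1.05 ± 0.36 (camera adjusted p = 0.00124, adjusted p = 0.431 with an estimated correlation). NK cell markers had a median of -0.39, with the granule protease Gzmb at -0.99 ± 0.42 (camera adjusted p = 0.0266, adjusted p = 0.494 with an estimated correlation). Platelet markers had a median of -0.23, with the adhesion receptor Selp at -1.06 ± 0.48 (camera adjusted p = 0.0248, adjusted p = 0.516 with an estimated correlation). Erythroid markers had a median of -0.27, with Trim10 at -0.71 ± 0.29 (camera adjusted p = 0.0368, adjusted p = 0.516 with an estimated correlation). B cell markers had a median of 0.21, with Spib at 1.57 ± 0.38 and Ms4a1, which encodes CD20, at 1.23 ± 0.37, both past the threshold when adjusted over the list alone (camera adjusted p = 0.0794). Another tested probe set had the opposite sign at 5 mg/kg for Brd3 (0.29), Ncl (-0.18), Ier5 (-0.47), Hsp90aa1 (-0.056), Bcl2l11 (-0.046) and Tcf4 (0.023). Several of the genes given for lists were above the floor on few arrays at 5 mg/kg (Cd27 on 1 of 5, Myc, Rtp4, Cd180 and Clec4e on 2, Gbp3, Gzmb, Ccr9, Tcf4 and Selp on 3), which makes their values depend on the floor.

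T cell markers had a median of 0.20 at 5 mg/kg (camera adjusted p = 0.1), and 11 of 15 members were higher. The costimulatory receptor Cd27 went against them, at -0.76 ± 0.24 (SE). Autophagy and lysosome genes had a median of -0.16 and Hexa, a lysosomal hexosaminidase, was at -0.97 ± 0.20 (camera adjusted p = 0.0641). Inflammatory cytokine and NF-kB genes had a median of -0.15, with the chemokine Ccl6 at -1.27 ± 0.32 (camera adjusted p = 0.226). Immediate-early genes had a median of 0.11, Ier5 being at 0.93 ± 0.24 and Klf4 at -0.75 ± 0.20 (camera adjusted p = 0.183). Cell cycle genes had a median of -0.14 while the replication clamp gene Pcna was at 0.89 ± 0.20 (camera adjusted p = 0.742), and BCL2 family and survival genes a median of -0.18 while the pro-apoptotic Bcl2l11 was at 0.68 ± 0.18 (camera adjusted p = 0.494). Glucocorticoid-induced genes had a median of 0.22 (camera adjusted p = 0.183) and housekeeping genes 0.20 (camera adjusted p = 0.226). For MYC and ribosome biogenesis genes, which included Ncl at 0.77 ± 0.23 and Dkc1 at -0.74 ± 0.19, the median was 0.02, the mean -0.0012 and camera's direction down (adjusted p = 0.993). For p53 targets the median was 0.02, the mean -0.0068 and camera's direction up (adjusted p = 0.742), and for circadian clock genes the median was -0.03, the mean 0.04 and the direction up (adjusted p = 0.507).

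**Figure D3:**
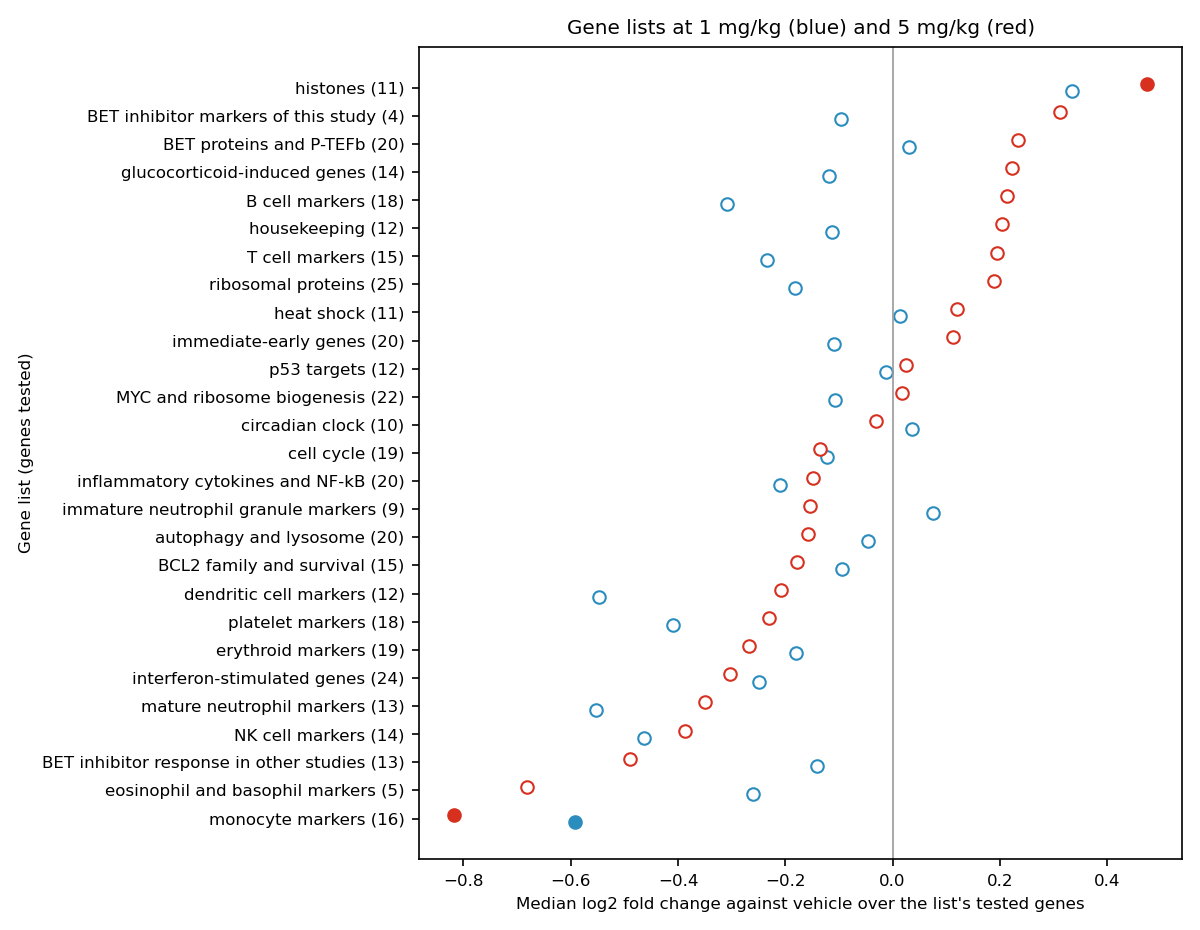
Median log2 fold change of each of the 27 gene lists at 1 mg/kg and 5 mg/kg against vehicle. Filled points passed an adjusted p of 0.05 with camera's estimated correlation, which were monocyte markers at both doses (-0.59 and -0.82) and histones at 5 mg/kg (0.48).

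At 1 mg/kg against vehicle, which asks what the lower dose does, Ear3 fell (log2 -2.57 ± 0.34, SE, n = 5 per group; limma adjusted p = 0.0171), staying above the floor on 3 of 5 arrays. It was the 1 gene past the threshold, with 0 higher. Sertad1 was at 1.20 ± 0.31 (adjusted p = 0.449), Slc25a24 at -1.21 ± 0.21 (adjusted p = 0.163), Pla2g7 at -1.44 ± 0.39 (adjusted p = 0.455) and Mpeg1 at -1.30 ± 0.31 (adjusted p = 0.379). Brd2 was at 0.60 ± 0.23 (adjusted p = 0.782) and at 1.15 in its other probe set, and Hexim1 at -0.11 ± 0.29 (adjusted p = 0.969) and 0.52 in the dimmer probe set. Myc was at -0.90 ± 0.36 and Il7r at -0.47 ± 0.20, also short of the threshold. At an unadjusted p under 0.05 there were 754 genes, 246 higher and 508 lower, against 625 from chance, and groups without overlap were seen for 0.904% of genes where chance gives 0.794%. Ear3 was lost, leaving 0 genes, without vehicle replicate 1, 3 or 4 and without 1 mg/kg replicate 1, 4 or 5 (limma; 590 to 885 genes at an unadjusted p under 0.05). Its call was lost in 18 of 33 alternatives in all (adjusted p = 6.1e-04 to 0.411), over which its value was -2.97 to -2.02. Without 1 mg/kg replicate 2 there were 2 genes, Ear3 and Tmem71 (-2.40, adjusted p = 0.00506), the latter named after its value was seen.

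Monocyte markers fell at 1 mg/kg as well. Of 16 members 15 were lower, with a median of -0.59, and 8 passed when adjusted over the list alone and 0 over all genes. Cd68 was at -1.46 ± 0.33 (SE), Fcgr4 at -1.0 ± 0.33, Ms4a6c at -0.97 ± 0.25 and Cybb at -0.60 ± 0.23. Camera's adjusted p was 1.8e-09, and adjusted p = 0.0276 with an estimated correlation, while fry's adjusted p was 0.00415 for one direction. The log2 18S signal and the mature neutrophil marker mean were lower on the same arrays. The estimated-correlation call was lost without vehicle replicate 4 (adjusted p = 0.0618) and without 1 mg/kg replicate 1 (0.057), 4 (0.0878) or 5 (0.0584), where the median was -0.55, -0.58, -0.58 and -0.49 and fry's adjusted p 0.00899 to 0.0168. It was also lost under 8 of 18 other settings, among them the 18S signal as a covariate (adjusted p = 0.104; fry 0.0267) and the mature neutrophil marker mean as a covariate (median -0.38; adjusted p = 0.17; fry 0.0956). Fry was also past 0.05 without scaling between arrays (0.899) and without the dimmest and the brightest array (0.0597).

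Camera with the preset correlation also called 7 lists lower at 1 mg/kg that were lost with an estimated correlation, and 0 of their members passed over all genes. Dendritic cell markers had a median of -0.55, with Ccr9 at -1.20 ± 0.32 (SE) and Tcf4 at -0.77 ± 0.25 (adjusted p = 0.144 with an estimated correlation). Mature neutrophil markers also had a median of -0.55 (adjusted p = 0.365 with an estimated correlation). Interferon-stimulated genes had a median of -0.25, with 2 members lower and 1 higher when adjusted over the list alone. They were Rtp4 at -1.22 ± 0.28, Gbp3 at -0.72 ± 0.21 and Oas2 at 1.18 ± 0.37, the last named after its value was seen (adjusted p = 0.518 with an estimated correlation). NK cell markers had a median of -0.46, platelet markers -0.41, B cell markers -0.31 and ribosomal protein genes -0.18 (adjusted p = 0.574 with an estimated correlation for each). The camera adjusted p with the preset correlation ran from 6.8e-04 for dendritic cell and platelet markers to 0.0333 for B cell markers. The histone median was 0.33 (camera adjusted p = 0.192). Signs differed for glucocorticoid-induced genes (median -0.12, mean 0.14, camera up), immature neutrophil granule markers (median 0.08, mean -0.05, camera down) and p53 targets (median -0.01, mean 0.06, camera up), none of them past the threshold.

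The direct comparison of 5 mg/kg with 1 mg/kg, which tests the dose difference itself, gave 0 genes by limma (smallest adjusted p = 0.453; 987 genes at an unadjusted p under 0.05, 658 higher and 329 lower, against 625 from chance). Sertad1 was 1.45 higher at 5 mg/kg on the log2 scale (adjusted p = 0.453), Spib 1.39 and Dpagt1 at -1.09 (adjusted p = 0.453 for Dpagt1). Groups without overlap were seen for 1.16% of genes where chance gives 0.794%. Leaving out vehicle replicate 3 gave 1 gene, Zbtb11 (1.33), and leaving out 5 mg/kg replicate 4 gave 1, Tiprl (1.20), both named after their values were seen.

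All 5 lists that the preset camera called higher at 5 mg/kg than at 1 mg/kg were lost with an estimated correlation. Ribosomal protein genes were higher in 25 of 25 members (median 0.39; camera adjusted p = 4.5e-10, adjusted p = 0.287 with an estimated correlation). B cell markers had a median of 0.54 and T cell markers of 0.46 (adjusted p = 0.397 with an estimated correlation for each). Histones had a median of 0.53 and BET and P-TEFb genes of 0.19 (adjusted p = 0.232 with an estimated correlation for each), and fry's adjusted p was 0.0416 for histones and for immediate-early genes (median 0.21). Monocyte markers had a median of -0.09 (camera adjusted p = 0.541). Signs differed for inflammatory cytokine and NF-kB genes (median 0.05, mean -0.02, camera up), glucocorticoid-induced genes (median -0.04, mean -0.0017, camera up), heat shock genes (median -0.0050, mean 0.08, camera up) and BCL2 family genes (median 0.03, mean -0.02, camera up), none past the threshold.

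The comparisons of the 2 doses with vehicle use the same vehicle arrays, so some likeness arises with no effect. The 1 gene called at both doses was Ear3, against 0.00064 from independent lists and 0 on average in 100 simulations of unchanged groups. Unchanged groups give almost no calls at either dose, so that average of 0 was close to fixed in advance. Across genes, which are not independent replicates, the covariance of the log2 fold changes was 0.0742 against a simulated mean of 0.0571 (0.0524 to 0.0622), a difference of 0.0171, and their correlation was 0.486 against a simulated 0.50. The simulations drew each gene independently, so their range does not allow for genes that vary together. A value above that range is therefore not evidence of a shared effect. With the vehicle arrays split between the comparisons in 20 ways, the median covariance was 0.0172 (-0.0201 to 0.0460), the median correlation was 0.0790 and 0 genes were called at both doses in any of the 20. Each dose then had only part of the vehicle arrays, which lowers the chance of any call. The 0 therefore does not decide whether the doses share a gene.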

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

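The tests of scaling and of 18S signal for the monocyte markers, and the tests of 18S signal and of mature neutrophils for the 11 genes past the threshold, were chosen only after the results were seen. The test of unequal falls among the monocyte markers and the splits of the arrays were set beforehand, though that the former excludes little was judged after its value was seen.

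Within a group of 5 arrays, 1 array stood apart from the other 4 in 14 of the 219 groups looked at, over 52 genes and the array measures, by a gap above Dixon's 95% limit. Chance gives about 1 in 20 such groups, or 11 here. With vehicle, replicate 1 had Fcgr4 at 5.84 (log2; the others 6.51 to 6.77), Rps6 at 4.86 (others 4.02 to 4.26) and an NK cell marker mean of 5.61 (others 6.25 to 6.50), and replicate 2 had Serpini1 at 5.05 with the others at the floor of 4. At 1 mg/kg, replicate 3 had Serpini1 at 4.64, Klf4 at 5.89 and Cd27 at 4.29, and replicate 5 had Pcna at 8.06 (others 8.52 to 8.70). At 5 mg/kg, replicate 5 had Myc at 4.80, Klf4 at 4.77, Clec4e at 4.89 and Cd27 at 4.31, and replicate 1 had Gbp3 at 4.81 and Alox15 at 7.47 (others 4 to 4.91). Several of these groups lay mostly at the floor, where a value just above it stands apart by construction.

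Among 4537 probe sets annotated with no gene or with several, which the gene comparisons do not use, 1 passed the threshold at 1 mg/kg (lower) and 5 at 5 mg/kg (2 higher and 3 lower), in a limma fit of all 24273 probe sets.

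Monocyte markers were lower at 5 mg/kg. The size of the shift depended little on scaling: the list median was -0.81, -0.82 and -0.73 with median, 75th percentile and no scaling (camera adjusted p at most 7.9e-11). Without scaling, however, the adjusted p was 0.817 with an estimated correlation and 0.953 by fry. On the unscaled arrays the markers, less genes of like brightness on the same array, gave a log2 difference of -0.77 from vehicle (exact permutation p = 0.00794, 5 arrays per group without overlap). That subtraction itself adjusts the level of each array, so it cannot decide whether scaling matters. The 18S difference stays open, since it runs with the groups: the median was -0.67 with log2 18S as a covariate and -0.80 without the 2 vehicle arrays of highest 18S signal, with fry's adjusted p at 0.0463 and 0.00824 and the estimated-correlation adjusted p at 0.175 and 0.11. Fewer monocytes with all their transcripts down alike may also account for it: the exact permutation p of unequal falls among the members was 0.238, in a test that found unequal falls in only 65% of simulated runs and so excludes little. An effect of the compound on transcription in monocytes is the biological alternative, and it cannot be told apart from the 18S difference or from fewer monocytes.

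The 11 genes past the threshold at 5 mg/kg kept their signs with log2 18S as a covariate, with a median absolute log2 fold change of 1.99 against 2.10, but the median SE grew from 0.304 to 0.468 and 0 of the 11 stayed past the threshold (all 11 had an unadjusted p under 0.05). The median fold thus changed little while the median error grew, and why the calls ended was not tested. Since 18S signal and group run together, a difference in 18S signal cannot be told apart from an effect of the dose on these genes. For the higher and the lower genes, each taken as a set, the tables argue against fewer mature neutrophils as the whole cause. With their marker mean as a covariate the 3 higher genes had a median log2 fold change of 1.66 (Sertad1 2.79 ± 0.37, H2ax 1.66 ± 0.26 and H2aw 1.47 ± 0.26, SE, against 2.66 ± 0.31, 1.46 ± 0.22 and 1.26 ± 0.23 without it), the first 2 past the threshold and H2aw not (adjusted p = 0.0859); its fold grew with its error, and why its call ended was not tested. The 8 lower genes fell by at least 1.16 (log2 -1.16 for Slc25a24, the smallest fall), whereas the 13 neutrophil markers had a median of -0.35 (SD 0.545 over the markers). The neutrophil marker Fpr2, at -1.34, fell by more than Slc25a24. With that covariate the median of the 8 genes was -1.91 against -2.16, and Ear3 alone of the 8 stayed past the threshold. Fewer monocytes stay open as a cause for the 8 lower genes, since no monocyte marker covariate was run. Monocyte markers had a median of -0.82 at 5 mg/kg, a smaller fall than the median of -2.16 of the 8 genes. The 3 higher genes rose while the monocyte markers fell, and a loss of monocyte transcripts does not by itself give a rise.

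Other splits of the same 10 arrays were compared with the real one, 100 per comparison with the real one included. At 5 mg/kg, 1 of 100 splits gave as many genes (11 in the real split, at most 5 in the others). That share is under the limit of 5 in 100, so by this limit alone chance is excluded for that count under the standard setting. The 1 split is the real one, so the share is the smallest that 100 splits allow. It is also 1 of 6 counts of splits, without adjustment over them. The splits were not run under other settings, where the count was 1 without scaling and 0 with the 18S covariate. As many lists by the preset camera came in 3 of 100 (10 in the real split, at most 11 in the others). Though under the limit, this does not exclude chance for the lists. It is a single share of 3 in 100 among 6 counts of splits, 2 other splits gave 11 lists, and 8 of the 10 were lost with an estimated correlation. At 1 mg/kg, 14 of 100 gave as many genes (1 in the real split, at most 2 in the others) and 5 of 100 as many lists (8 in the real split, at most 10 in the others), so chance cannot be excluded. Between the doses 22 of 100 gave as many lists (5 in the real split, at most 9 in the others), so chance cannot be excluded there either. For genes the real count between the doses was 0 (limma, 987 at an unadjusted p under 0.05; at most 2 in the others), so that all 100 reach it by construction and the splits test nothing.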

How the results depend on the processing

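The tests without scaling, with floors of 8 and 32, with genes above the floor on at least 1 array, without the dimmest and brightest or the highest-18S vehicle arrays, and with 18S as a covariate were chosen only after the results were seen. No named gene past the threshold changed sign under any setting run for it. At 1 mg/kg the count (1, Ear3) became 0 with the brighter 50% of genes, array weights, only the groups compared, the erythroid, mature neutrophil or B cell covariate, an adjusted p under 0.01, no scaling, genes above the floor on at least 1 array, no dimmest and brightest array, or the 18S covariate (limma; 142 to 926 genes at an unadjusted p under 0.05). The 1 gene was Cenpv, higher (1.76), with a floor of 8, and Akirin1, higher (3.06; its other probe set was at 0.079 with all arrays), without the 2 vehicle arrays of highest 18S signal, both named after their values were seen. At 5 mg/kg the count (11) became 33 with mean probe sets, 32 with each probe set counted on its own, 65 with array weights (27 higher, 38 lower), 18 with only the groups compared, 17 with the B cell covariate, 45 with a floor of 32, 22 with genes above the floor on at least 1 array and 17 without the dimmest and brightest array. It became 3 with the mature neutrophil covariate, 3 without the 2 vehicle arrays of highest 18S signal, 1 without scaling, where the median of all genes moved to 0.102, and 0 with the 18S covariate (limma; 1077 at an unadjusted p under 0.05). Between the doses the count (0; limma, 987 at an unadjusted p under 0.05) became 1 with a floor of 8 (Cenpv, -1.79). Genes called at both doses (1) became 0 without scaling, with the brighter 50% of genes, with an adjusted p under 0.01 and with the vehicles split. With the brighter 50% of genes Ear3 was itself left out, as its mean log2 of 5.36 lay below the limit of 5.62. The count of 0 at 1 mg/kg and at both doses is therefore fixed there and is not a lost call. Dpagt1, Ptpro and Slc25a24 were left out in the same way. The stricter limit of 0.01 lies under the adjusted p of Ear3 at 1 mg/kg (limma, 0.0171). For the other settings the cause was not tested.

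Leaving out each array gave 0 to 2 genes at 1 mg/kg, 8 to 22 at 5 mg/kg and 0 to 1 between the doses. It was 0 at 1 mg/kg without vehicle replicate 1, 3 or 4 or 1 mg/kg replicate 1, 4 or 5, 2 without 1 mg/kg replicate 2, and at 5 mg/kg 19 without 1 mg/kg replicate 1 and 22 without replicate 5. Between the doses it was 1 without vehicle replicate 3 or 5 mg/kg replicate 4. At 5 mg/kg, H2aw was lost in 22 of 34 settings (adjusted p = 0.015 to 1.00), Slc25a24 in 21 of 33 (0.0123 to 1.00) and Ccr1 in 14 of 34 (0.00615 to 0.977), each of the other 8 genes in 1 to 5.

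With the mature neutrophil covariate the list medians turned for mature neutrophils (0.072 at 1 mg/kg and 0.054 at 5 mg/kg), NK cells (0.15 at 5 mg/kg) and platelets (0.077 at 5 mg/kg), and camera's direction turned for NK cells at 1 mg/kg (-0.039). With the B cell covariate it turned for B cells at 1 mg/kg (-0.011). None passed the threshold there, and a list's own mean as the covariate removes that list's shift by construction.

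Replicate numbers gave no clear sign of pairing. After each gene's group mean was taken off, 3 of 15 same-number pairs of arrays correlated above 0.1 (-0.28 to 0.35). Among arrays of the other groups, 4 of 15 arrays correlated best with an array of their own number. No chance level was computed for these counts. With the replicate block, 0 genes passed at 1 mg/kg (limma; 748 at an unadjusted p under 0.05), 9 at 5 mg/kg and 0 between the doses (933 at an unadjusted p under 0.05), and 0 were shared by both doses. The alternative floor at the 25th percentile was not run, since that percentile was -1.94. Signal over background limits what can be seen: 52.7% of probe set values lay at the floor.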

Other observations

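The tests of splicing factor and C-type lectin genes were chosen only after Tra2a, Hnrnpa2b1, Clec4a3, Clec7a and Clec4e had been seen among the smallest p at 5 mg/kg; the other members, on which the tests ran, had not been seen.

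When each probe set was counted on its own, 32 passed at 5 mg/kg against vehicle, and they added genes to those named by the rule, chosen here after their values were seen. Tgfbi, an extracellular matrix protein made by monocytes and macrophages, was lower in 3 probe sets (-1.42, -1.71 and -1.41), as were Ms4a6d (-1.34), the actin-capping protein Capg (-1.51), and the adaptor Sla (-2.22, with 3 other sets at -0.59 to -1.14). Single probe sets were also lower for Il1rn, the interleukin-1 receptor antagonist (-1.09, but 0.38 in its brightest set and -0.55 in another), and for Ccr2 (-2.62, but -1.77 in its brightest set and 0.18 in another). Higher were a dimmer Hexim1 probe set (1.86), a Bcl2l11 probe set (1.48, with 3 others at -0.046 to 0.68) and Setd2, the histone H3 lysine methyltransferase (1.11). Apart from the sets given as other, brightest or another, each had a limma adjusted p under 0.05 over 19736 probe sets (n = 5 per group).

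Tra2a, a splicing regulator, passed in that count (0.99 ± 0.18, SE). Hnrnpa2b1 was at 0.99 in its brightest probe set and at 0.95 and 0.81 in others, but at -0.83 in another. A hypothesis was that splicing factor genes of the Srsf, Hnrnp and Tra2 families are higher at 5 mg/kg. The median of the 24 other members was 0.16, the direction it needs, with a camera adjusted p of 0.0188 but adjusted p = 0.529 with an estimated correlation and a fry adjusted p of 0.455, so a shared rise may or may not be there. For the 7 other C-type lectin genes, the median was -0.069 and the mean 0.05, with camera's direction up (adjusted p = 0.613), which did not decide whether that family is lower.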
